A study of Mus musculus with 12 samples.

How the data were processed

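Single-cell RNA-seq of CD45+ CD11b++ brain macrophages sorted from the hippocampus was available for 12 libraries, 3 in each of 4 groups (control or anti-Caspr2 in utero, with saline or captopril). Per the labels' protocols, tissue was dissociated enzymatically, myelin was removed with beads, cells were stained for viability, CD45 and CD11b and sorted, and libraries were made with 10x 3′ chemistry at a stated median of about 38000 reads per cell. The deposited values are raw UMI counts per gene and barcode, made by the authors with Cell Ranger 6.0.0 against GRCm38, per the submitters' processing notes. Whether introns were counted, and which annotation was used, is not given in the sources used here. Cell names were rebuilt here from markers. The files held 29388 barcodes and 139660949 UMIs, 739812 to 18185418 per library, with a median of 3945 to 8265 UMIs per kept cell.

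Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept. Scrublet, at a doublet rate of 0.06, called 109 cells (0.431%), so doublet calling has not worked. Its 41 calls in 3 libraries were removed, 4107 barcodes failed the filters and 25240 cells remained, in which doublets may persist. Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 in Python 3.11.15 (2000 variable genes, 30 components, 15 neighbours, resolution 1.0). Clusters were named from marker lists for microglia, border-associated macrophages, monocytes and neutrophils. In 5 clusters (2728 cells) no name was given, and 3 of these (2355 cells) were shallow clusters with few UMIs per cell.

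Raw counts were summed per library over microglia-like cells and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust, TMM factors, edgeR's filter on low counts, a mean per group and no covariate), with Benjamini-Hochberg adjusted p under 0.05 over 12231 genes and 8 comparisons fitted from all 12 libraries. Log2 fold changes are edgeR's and CPM were computed here with TMM factors. For 25 gene lists camera in limma 3.58.1 was used with a preset correlation of 0.01, then with an estimated correlation and fry. Shares were tested by exact permutation, adjusted within their family. Correlations across genes were set beside 20 simulations of unchanged groups. The code was tested on simulated data with 200 changed genes in 3 draws: it recovered 88.1% of genes changed 2-fold for captopril averaged over exposure, with 11.7 unchanged genes called per draw, and 83.6% for exposure averaged over drug.

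The rule for named genes, the gene lists, the markers, the tests and most alternatives were chosen before the data were examined. For each comparison the rule named up to 12 higher and 12 lower genes with the largest change, among genes past the threshold with a mean of at least 20 CPM, no overlap between the groups and a symbol that is not a predicted gene. With fewer than 12 genes past the threshold it took the 12 with the smallest p at that mean. It added up to 4 members with the smallest p of each list past the threshold, up to 2 highly expressed members of other lists, and a fixed set of microglial, sex-linked and target genes. The text gives some of these. Of the 56 genes called for captopril averaged over exposure, 30 had at least 20 CPM, and 7 higher and 9 lower met the rule. In all 37 alternatives were tried, including DESeq2 1.42.0 with its size factors, limma-voom, other gene and cell filters, surrogate variables with sva 3.50.0, a block on mouse number and leaving out each library. Drug cannot be separated from the first number of the library names. No pair of replicates looked like a duplicate, with a chi-square per gene of 3.80 to 34.3.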

Results

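Single-cell RNA was measured in brain macrophages sorted as CD45+ CD11b++ cells from the hippocampus of C57BL/6 mice aged postnatal day 42 to 45. Mice had been exposed in utero to control or anti-Caspr2 antibody and then received saline or captopril. Caspr2 is a neuronal cell adhesion protein encoded by Cntnap2, and captopril is an inhibitor of angiotensin-converting enzyme. Each of the 4 groups held 3 mice, each from its own litter, with 1 library per mouse. The 12 libraries held 29388 barcodes and 139660949 unique molecular identifiers (UMIs), with 739812 to 18185418 UMIs per library. Anti-Caspr2 saline mouse 3 stood apart with 91 barcodes, against 875 to 4059 in the others. Anti-Caspr2 saline mice 1 and 2 had 875 and 1430 barcodes. Control saline mice 1, 2 and 3 had more, with 2223, 3367 and 3653, as had anti-Caspr2 captopril mice, with 2037, 2540 and 3138. Exposure in saline and captopril in exposed mice therefore cannot be told apart from the number of barcodes. All captopril libraries carried 2 as the first number of their library name and all saline libraries carried 3, so drug and this number cannot be told apart in any captopril comparison. The exposure comparisons within each drug do not cross this number. In the interaction, a shift shared by both exposure groups cancels. An exposure effect that varies with this number cannot be told apart there from one that varies with drug.

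Clustering of 25240 cells gave 17 clusters, of which 8 were microglia-like, holding 20801 cells and 118553394 UMIs. In 3 of these clusters (3890, 2205 and 3372 cells) the homeostatic list had the most members among the 50 leading genes, with 9, 15 and 8. Only the second had P2ry12 and P2ry13 among its 10 leading genes, while Hes1 was first in the first and Arl10 in the third. Heat shock genes led 4046 cells, and immediate early genes such as Fosb and Egr1 led 3980 cells. Cytokine and NF-kB genes such as Tnf and Ccl3 led 2481 cells, interferon response genes such as Ifit3 and Isg15 led 230 cells, and no fixed list led the remaining 597 cells. Border-associated macrophage-like cells with Mrc1, Pf4 and Ms4a7 numbered 710, neutrophil-like cells with S100a8 and S100a9 numbered 693, and monocyte-like cells with Plac8 and Ly6c2 numbered 308. Control saline mouse 2 held 656 of the neutrophil-like and 247 of the monocyte-like cells, so no difference between groups is read from these classes, although their shares count among the 4 adjusted together. In that library the neutrophil markers summed to 633 CPM (counts scaled to library size) even within microglia-like cells, against 191 to 257 CPM in the other 11. Microglia-like cells gave 4955947 to 14540779 UMIs in 11 libraries, and 55 cells with 618688 UMIs in anti-Caspr2 saline mouse 3. The median UMIs per microglia-like cell were 7786, 6568.5 and 10318 in anti-Caspr2 saline mice 1, 2 and 3. They were 5844, 5096 and 4618 in control saline mice and 6092, 5485 and 3972 in anti-Caspr2 captopril mice. Depth per cell therefore cannot be told apart from exposure in saline or from captopril in exposed mice. Cntnap2 itself had 0 to 6 UMIs per library in microglia-like cells and Ace, the gene of the captopril target, had 0 in each, so neither could be tested at this depth. A count of 0 UMIs does not show absence of expression. Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 12 libraries, and Xist had at most 4 UMIs in any.

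The first comparison asked how exposure changed microglia-like cells without drug, setting anti-Caspr2 saline against control saline. Microglial identity genes lay close together in the 2 groups. P2ry12, a purinergic receptor of surveying microglia, had 2528 ± 70.1 CPM in controls and 2354 ± 161 CPM after exposure (SD, n = 3 each), a log2 fold change of −0.10 (95% interval −0.37 to 0.17). Tmem119, a microglial surface protein, gave −0.10 (95% interval −0.31 to 0.12) and the fractalkine receptor gene Cx3cr1 gave 0.01 (95% interval −0.25 to 0.26). Among the genes with the smallest p, Elavl4, which encodes a neuronal RNA-binding protein, had 19.99 ± 0.792 CPM in controls and 29.4 ± 0.845 CPM in exposed libraries (log2 fold change 0.57, SE 0.11). Ccl12, a chemokine that attracts monocytes, had 168 ± 39.6 and 97.0 ± 5.69 CPM (log2 fold change −0.77, SE 0.14), and Tmem88, an inhibitor of Wnt signalling, had 20.5 ± 1.40 and 32.0 ± 1.56 CPM (0.67, SE 0.13). None of these passed, each with an adjusted p of 0.320 in edgeR's quasi-likelihood test. The 3 libraries of one group did not overlap the 3 of the other for any of them. These genes were picked for their small p, so this is no further support for them. Tspo, a mitochondrial outer membrane protein, at −0.63 (SE 0.14), and H2-Q10 at 0.53 (SE 0.12) did not overlap either and did not pass, both at an adjusted p of 0.479.

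Gene lists moved in the same comparison with camera's preset correlation. Of the interferon response list, 28 of 29 genes lay below 0 with a median log2 fold change of −0.59, 0 passing over all genes and 9 when adjusted over the list alone (list adjusted p = 4.54e-12, and adjusted p = 0.632 with an estimated correlation). Its members include Bst2, which tethers virions, at 118 ± 14.98 against 78.3 ± 12.2 CPM (log2 fold change −0.54) and Rtp4 at 14.9 ± 4.68 against 6.18 ± 1.66 CPM (−1.31). Of the disease-associated microglia list, 23 of 26 genes lay below 0 with a median of −0.21 and 0 passing when adjusted over the list alone (adjusted p = 0.000133, and adjusted p = 0.632 with an estimated correlation). Trem2, a lipid-sensing receptor, and the tetraspanin gene Cd63 each gave −0.30. The list's mean log2 deviation from each gene's average was 0.22, 0.54 and 0.07 in control saline mice 1, 2 and 3. It was −0.29, 0.25 and −0.07 in anti-Caspr2 saline mice, so the groups overlapped. By this measure the heat shock and ribosomal lists below overlapped too, while the interferon and homeostatic lists did not. Homeostatic genes lay below 0 in 23 of 29 cases, median −0.13, with 0 passing when adjusted over the list alone (adjusted p = 0.000851, and adjusted p = 0.632 with an estimated correlation), among them Cst3, a secreted protease inhibitor, at −0.32 (SE 0.14). Heat shock genes lay above 0 in 18 of 19 cases, median 0.28, with Hspa1b at 0.86 (SE 0.43; list adjusted p = 0.000492, and adjusted p = 0.632 with an estimated correlation). Ribosomal protein genes went both ways. Their median was −0.15 with 56 of 78 below 0 (adjusted p = 0.000275, and adjusted p = 0.632 with an estimated correlation), while Rps29 and Rps27 gave 0.62 and 0.74, and 17 passed when adjusted over the list alone. The other lists past the threshold, all lower, were phagocytic receptors, lysosome, mitochondrially encoded and nuclear-encoded oxidative phosphorylation genes, with medians of −0.15, −0.10, −0.39 and −0.10 and adjusted p = 0.632, 0.632, 0.632 and 0.712 with an estimated correlation. The mitochondrially encoded list had an adjusted p = 0.829 and the other direction without anti-Caspr2 saline mouse 3, which held 55 microglia-like cells, and an adjusted p = 0.0844 without control saline mouse 1. In all, 0 of 12231 genes passed with edgeR, against 1172 at an unadjusted p under 0.05, 13 with DESeq2 and 0 with limma-voom, and 9 of 25 lists passed with the preset correlation and 0 with the estimated one or the directional test of fry. For 2858 genes (23.4%) the groups did not overlap, where chance gives 10% on average over all splits. Genes vary together, so a single split can lie away from this average without any effect. The spread over splits was not computed, here or for the shares without overlap given below. In simulated data of this design 65.2% of genes changed 2-fold were called and 29.9% of genes changed 1.5-fold. Control saline mouse 1 held the highest interferon level of all libraries, and without it the median of that list was −0.27, while without the cells of the interferon-led cluster it was −0.24.

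**Figure D1:**
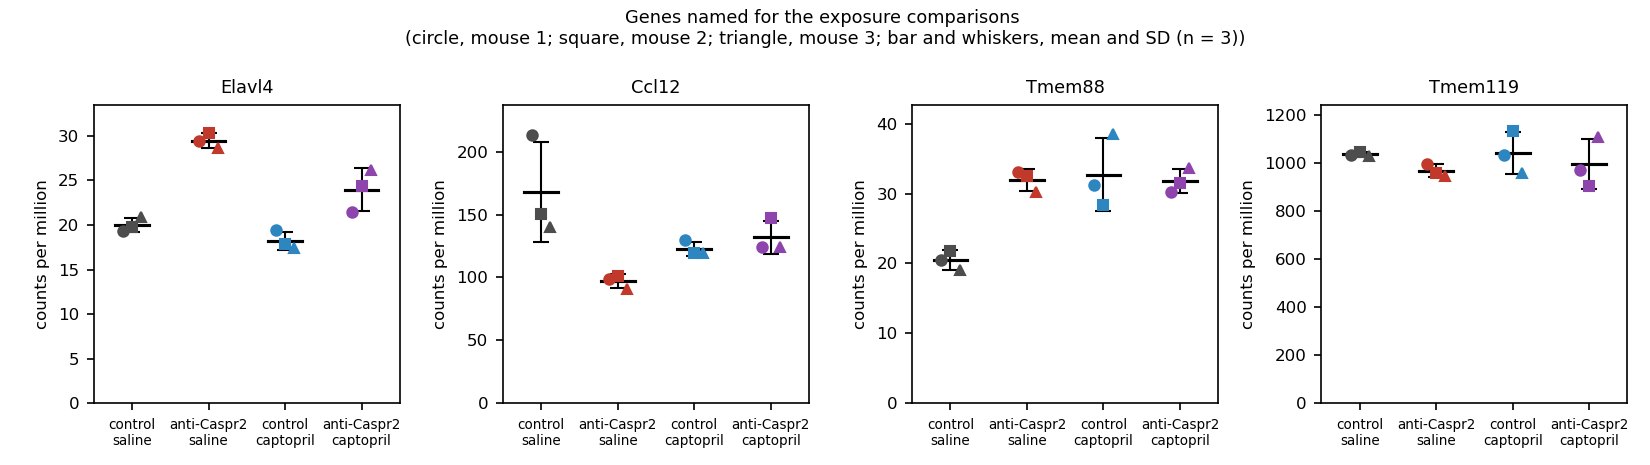
CPM in microglia-like cells of Elavl4, Ccl12, Tmem88 and Tmem119 in the 12 libraries, by group. Points are mice and bars are means with SD (n = 3); Elavl4 had means of 19.99 and 29.4 CPM in control and exposed saline libraries and of 18.2 and 24.0 CPM in control and exposed captopril libraries.

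The next comparison asked what exposure did under captopril, setting anti-Caspr2 captopril against control captopril. Elavl4 was again higher in every exposed library, at 24.0 ± 2.40 against 18.2 ± 1.02 CPM (log2 fold change 0.40, SE 0.10, n = 3 each). Gm42418, a noncoding transcript that overlaps AY036118 on the opposite strand in sequence of the ribosomal RNA precursor, had 889 ± 98.3 CPM in exposed and 1767 ± 546 CPM in control libraries (−0.99, SE 0.19), and AY036118 gave −0.43 (SE 0.14). The transcription factor gene Hlf gave −0.46 (SE 0.14). Nuclear-encoded oxidative phosphorylation was the one list past the threshold, with 65 of 77 genes below 0, a median of −0.08 and 0 passing when adjusted over the list alone (adjusted p = 1.38e-06, and adjusted p = 0.935 with an estimated correlation). Its members Ndufa7 and Ndufa3, subunits of respiratory complex I, gave −0.26 (SE 0.09) and −0.40 (SE 0.15). With edgeR 0 of 12231 genes passed, 327 had an unadjusted p under 0.05, DESeq2 gave 1 and limma-voom 0, and the groups did not overlap for 853 genes (6.97%, against 10% by chance). The list count rose to 3, 7, 3, 4 and 5 without control captopril mouse 1 or 3 or anti-Caspr2 captopril mouse 1, 2 or 3.

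Averaged over drug, exposure left Elavl4 highest in rank, at 0.48 (SE 0.07), higher in 6 of 6 exposed libraries than in all controls, with an adjusted p of 0.112 in edgeR. Since it was picked as first in rank, the lack of overlap is no further support. Elavl4 passed with DESeq2 (adjusted p = 0.00615) and with 2 surrogate variables added to the fit after the result was seen (adjusted p = 0.0121). Over all alternatives its adjusted p was 0.00615 to 0.824. Elavl4 lies on chromosome 4 from 110203722 to 110351909 on the minus strand (GRCm38). Tspo gave −0.35 (SE 0.10), Bst2 −0.33 (SE 0.09) and Cd63 −0.17 (SE 0.07). Heat shock genes lay above 0 in 19 of 19 cases (median 0.19), interferon genes below 0 in 27 of 29 (median −0.21), disease-associated genes below 0 in 22 of 26 (median −0.10), homeostatic genes below 0 in 24 of 29 (median −0.10) and nuclear-encoded oxidative phosphorylation genes below 0 in 65 of 77 (median −0.09). These 5 were among 10 lists past the threshold, 2 higher and 8 lower, each of these 5 with an adjusted p = 0.659 with an estimated correlation. With edgeR 0 of 12231 genes passed, against 927 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom, and 38 genes (0.311%) did not overlap between 6 and 6 libraries, where chance gives 0.216%. Across genes, the fold changes of exposure in saline and in captopril, which share no library, had a Pearson r of 0.129 and a Spearman rho of 0.207 with a covariance of 0.0101. Simulated unchanged groups gave an r of 0.00290 and a covariance of 0.000201, and genes are not independent replicates. The r was 0.0225 without anti-Caspr2 saline mouse 1, 0.0297 and 0.0476 without control captopril mouse 1 or 2, 0.0574 and 0.0271 without anti-Caspr2 captopril mouse 1 or 2, and −0.0325 over all cells in place of microglia-like cells. Over genes of at least 20 CPM it was 0.329. Other splits of the captopril libraries, tried after the result was seen, gave an r of −0.207 to 0.313 with exposure in saline. Of 100 splits of all libraries, 16 reached 0.129, the real one included. The simulated value therefore does not exclude chance.

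Whether the exposure effect differed with drug was tested as the interaction. Genes of the interferon list lay above 0 in 28 of 29 cases with a median of 0.75, meaning that they were lower after exposure in saline libraries but not in captopril libraries (adjusted p = 3.11e-13, and adjusted p = 0.731 with an estimated correlation). Usp18, an interferon-induced protease, gave 1.54 (SE 0.48). The saline side of this difference had a median of −0.59 for the list. That median was −0.27 without control saline mouse 1 and −0.24 without the cells of the interferon-led cluster. Disease-associated genes lay above 0 in 22 of 26 cases (median 0.16, adjusted p = 0.00892) and ribosomal protein genes in 55 of 78 (median 0.17, adjusted p = 0.00182), both with an adjusted p = 0.731 with an estimated correlation. Single genes with the smallest p were Pdcd11, a ribosome biogenesis factor, at −0.90 (SE 0.17), Rps29 at −0.94 (SE 0.18), Ccl12 at 0.87 (SE 0.19) and H2-Q10 at −0.73 (SE 0.17), while Cd63 gave 0.26 (SE 0.13). With edgeR 0 of 12231 genes passed, with a smallest adjusted p of 0.713, against 565 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom. The 3 lists became 9 without anti-Caspr2 saline mouse 2, 6 and 7 without control captopril mouse 1 or 2, and 6 and 5 without anti-Caspr2 captopril mouse 2 or 3.

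**Figure D2:**
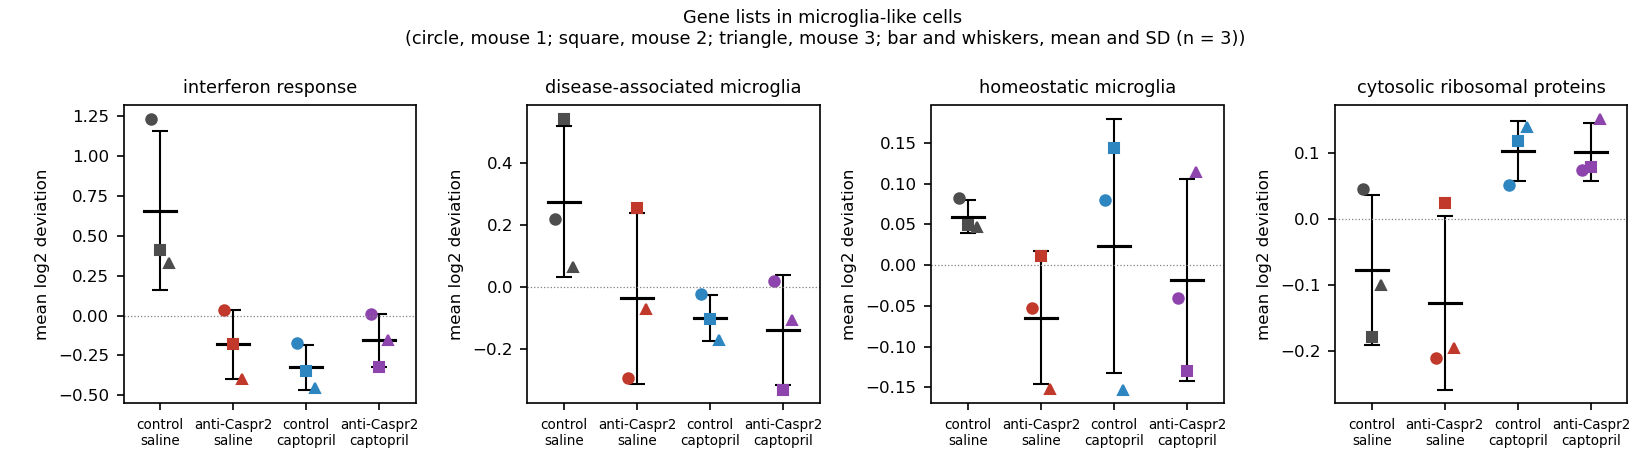
Mean log2 deviation from the gene's average over all libraries for 4 gene lists in microglia-like cells, by group. Points are mice and bars are means with SD (n = 3); the interferon list averaged 0.66 in control saline libraries, with control saline mouse 1 at 1.23, and −0.18, −0.32 and −0.16 in anti-Caspr2 saline, control captopril and anti-Caspr2 captopril libraries.

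Captopril in exposed mice was compared as anti-Caspr2 captopril against anti-Caspr2 saline, the comparison closest to the series' question of whether the drug restores microglial homeostasis. H2-Q10, a secreted class I histocompatibility protein, fell from 37.9 ± 4.53 to 15.8 ± 1.27 CPM (log2 fold change −1.28, SE 0.12, adjusted p = 0.000426, lower in 3 of 3 libraries). Lars2, the mitochondrial leucyl-tRNA synthetase, fell from 119 ± 30.1 to 47.7 ± 8.10 CPM (−1.25, SE 0.16, adjusted p = 0.00738). Gm42418 fell from 2341 ± 362 to 889 ± 98.3 CPM (−1.39, SE 0.19, adjusted p = 0.0147), and Fam71a, which was chosen after its values were seen because it lies below the minimum of 20 CPM for named genes, rose from 2.36 ± 2.09 to 19.2 ± 1.36 CPM (2.52, SE 0.35, adjusted p = 0.0147). P2ry12, Tmem119 and Cx3cr1 gave 0.01 (95% interval −0.26 to 0.28), 0.04 (95% interval −0.17 to 0.25) and −0.00 (95% interval −0.26 to 0.25), and Apoe, a lipid carrier of activated microglia, gave −0.68 (95% interval −1.42 to 0.06, adjusted p = 0.492). Without anti-Caspr2 saline mouse 3, which held 55 microglia-like cells, the change of Apoe was −0.25, and over all settings it was −1.01 to −0.02. Ribosomal protein genes lay above 0 in 66 of 78 cases, median 0.29, with 47 passing when adjusted over the list alone and 0 over all genes, such as Rpl8 at 0.46 and Rpl18 at 0.41 (list adjusted p = 4.54e-24, and adjusted p = 0.702 with an estimated correlation). Immediate early genes lay above 0 in 24 of 28 cases, median 0.23, with the stress phosphatase subunit gene Ppp1r15a at 0.44 (list adjusted p = 2.77e-05, and adjusted p = 0.802 with an estimated correlation). The exposed captopril libraries split, with mean log2 deviations of 0.36, 0.23 and −0.12 in mice 1, 2 and 3 against −0.15, −0.08 and 0.18 with saline, and an immediate early cluster of 47.0%, 48.4% and 4.52% against 22.4%, 12.96% and 21.8%. Unfolded protein response genes lay above 0 in 16 of 17 cases, median 0.13, with the chaperone gene Hsp90b1 at 0.32, and oxidative stress genes in 19 of 28, median 0.15 (adjusted p = 0.593 and 0.779 with an estimated correlation). Of 25 lists these 4 passed with the preset correlation, all higher, and 0 with the estimated one. Of the lists past the threshold for exposure in saline, only ribosomal proteins passed here. The homeostatic, disease-associated and interferon lists did not pass. Their mean log2 deviations were −0.06, −0.04 and −0.18 in anti-Caspr2 saline and −0.02, −0.14 and −0.16 in anti-Caspr2 captopril libraries. Nfkbia, the NF-kB inhibitor, gave 0.59 (SE 0.11) with an adjusted p of 0.0884.

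With edgeR the 4 genes were 1 higher and 3 lower of 12231, against 1356 at an unadjusted p under 0.05, 63 with DESeq2 and 3 with limma-voom, and 1956 genes (16.0%) did not overlap, where chance gives 10%. The count was 1 without anti-Caspr2 saline mouse 1, 2 without anti-Caspr2 captopril mouse 2 and 0 over all cells. H2-Q10 belongs to a family of close class I paralogs and Gm42418 overlaps AY036118, so their counts are uncertain. Gm42418 was also among the 10 leading genes of shallow clusters 6 and 10. Shallow clusters held 22.05% of cells in anti-Caspr2 saline and 3.98% in anti-Caspr2 captopril libraries. These clusters were left out of the tested sums, and with them added the log2 fold change of Gm42418 was −1.67. Whether RNA like theirs within microglia-like cells adds to the fall of Gm42418 was not tested. H2-Q10 lies on chromosome 17 from 35470089 to 35474563 (plus strand), Lars2 on chromosome 9 from 123366927 to 123462666 (plus strand) and Fam71a on chromosome 1 from 191162584 to 191164817 (minus strand, GRCm38). To ask whether captopril opposed the exposure effect, fold changes of exposure in saline and of captopril in exposed mice were correlated across genes. Both contain the anti-Caspr2 saline libraries with opposite sign, so a negative value is given by chance. The Pearson r was −0.535 with a covariance of −0.0652, while unchanged simulated groups gave an r of −0.669 and a covariance of −0.0571 ± 0.00242 (SD of 20 simulations), leaving a difference of −0.00803. The simulation drew each gene independently, while genes of a library vary together, so its SD does not hold that spread. The r was weaker than simulated and the covariance larger in size. No opposition by captopril is therefore read from these values. The r was −0.338 over genes of at least 20 CPM and −0.248 over all cells, both over 1.5 times smaller.

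In control mice, captopril was compared with saline to ask what the drug did without exposure. Interferon response genes lay below 0 in 29 of 29 cases with a median of −0.66, 0 passing over all genes and 24 when adjusted over the list alone (adjusted p = 2.28e-23, and adjusted p = 0.216 with an estimated correlation). The median was −0.47 without control saline mouse 1 and −0.32 without the cells of the interferon-led cluster. Usp18 gave −1.61 (SE 0.30). Disease-associated genes lay below 0 in 24 of 26 cases, median −0.23, with Axl, a receptor for dying cells, at −1.13 (SE 0.21) and Cst7, a cystatin, at −0.64 (SE 0.13; list adjusted p = 5.57e-08, and adjusted p = 0.329 with an estimated correlation). Immediate early genes lay above 0 in 28 of 28 cases, median 0.26, with Ier5 at 0.43 (list adjusted p = 5.57e-08, and adjusted p = 0.329 with an estimated correlation). Their mean log2 deviation was −0.06, −0.05 and 0.27 in control captopril mice 1, 2 and 3 and −0.12, −0.27 and −0.20 in control saline mice, so mouse 3 stood apart, as did its immediate early cluster with 43.1% of microglia-like cells against 7.39% and 8.45% in mice 1 and 2. Glucocorticoid response genes lay above 0 in 15 of 15 cases, median 0.29, with Ddit4, an inhibitor of mTOR signalling, at 1.16 (adjusted p = 0.216 with an estimated correlation). Ribosomal protein genes lay above 0 in 60 of 78 cases, median 0.10, with Rps29 at 0.65 (adjusted p = 0.372 with an estimated correlation), but over all cells in place of microglia-like cells this list moved the other way (adjusted p = 0.0181). The class II list was lower with 7 of 9 genes below 0, including H2-Aa at −2.41 (SE 0.43), which is also a leading gene of the border-associated macrophage-like cluster (adjusted p = 0.354 with an estimated correlation). Single genes with the smallest p were Klf10, a transforming growth factor-induced transcription factor, at 0.71 (SE 0.12), Tmem88 at 0.68, Khdrbs3, a splicing regulator, at 0.46, Rptor, the raptor subunit of an mTOR complex, at −0.45 and Lars2 at −0.76, none of which passed (adjusted p = 0.0894 for each in edgeR).

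In this comparison 0 of 12231 genes passed with edgeR, against 1157 at an unadjusted p under 0.05, 64 with DESeq2 and 0 with limma-voom, and 2174 genes (17.8%) did not overlap, where chance gives 10%. The count was 1 without anti-Caspr2 saline mouse 3, 4 without control captopril mouse 3 and 36 without anti-Caspr2 captopril mouse 3. The first and last of these lie outside the groups compared. They can act only through the variance, the filter on low counts and the scaling, which the fit takes from all libraries. Which of these moved the count was not tested. Of 25 lists 15 passed with the preset correlation, 6 higher and 9 lower, and 0 with the estimated one.

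Averaged over exposure, captopril changed 56 genes, 17 higher and 39 lower (edgeR, adjusted p under 0.05, 6 libraries against 6). H2-Q10 fell by 0.91 on the log2 scale (SE 0.08, adjusted p = 0.000199) and Lars2 by 1.00 (SE 0.11, adjusted p = 0.00103), each lower in 6 of 6 captopril libraries than in all saline libraries. Rptor fell from 108 ± 2.74 and 97.5 ± 10.2 CPM in control and exposed saline libraries to 78.8 ± 4.72 and 77.6 ± 3.86 CPM (−0.40, SE 0.06, adjusted p = 0.0149). The lower genes also included the histone demethylase gene Kdm3b (−0.28), the DNA methyltransferase gene Dnmt3a (−0.27), the splicing factor gene Rbm4 (−0.34) and the noncoding RNA Lncpint (−0.34). Lncpint was among the 10 leading genes of the microglia-like cluster with no leading list and of shallow cluster 6. Of the 10 leading genes of shallow clusters 6, 7 and 10, this comparison called 3, 1 and 2. Madd (−0.35), an activator of Rab proteins, and the adenylate cyclase gene Adcy7 (−0.34) were lower as well. Higher genes were Hbegf, a growth factor (0.78, SE 0.14, adjusted p = 0.0399), Nfkbia (0.45, SE 0.07, adjusted p = 0.0222) and Khdrbs3 (0.41, SE 0.06, adjusted p = 0.0111). The elongation factor gene Eef1b2 (0.33), Rpl31 (0.40), Utp3 (0.37) and the vesicle trafficking gene Trappc6b (0.31) were higher too. For each of these 16 genes all 6 captopril libraries lay on one side of all 6 saline libraries. The rule for named genes required this, so it is no further support for them. Their adjusted p values in edgeR ranged from 0.000199 to 0.0486.

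Outside the rule for named genes, and chosen after their values were seen, Fam71a (2.02, SE 0.23, adjusted p = 0.00198) and Adm (1.62), which encodes the vasodilator peptide adrenomedullin, were higher at low counts, Klf10 was higher (0.44), and H2-Aa (−1.65) and Gm42418 (−0.88) were lower (edgeR). Ribosomal protein genes lay above 0 in 78 of 78 cases, median 0.20, with 1 passing over all genes and 36 when adjusted over the list alone (list adjusted p = 5.42e-27, and adjusted p = 0.300 with an estimated correlation). Rps25 gave 0.36 (SE 0.07, adjusted p = 0.0510 in edgeR), and counts of ribosomal protein genes are uncertain because they have many pseudogenes. Immediate early genes lay above 0 in 27 of 28 cases, median 0.26, with 9 passing when adjusted over the list alone and Ppp1r15a at 0.33 (list adjusted p = 7.48e-09, and adjusted p = 0.300 with an estimated correlation). The captopril libraries split, with the immediate early cluster at 43.1% in control captopril mouse 3 and 47.0% and 48.4% in anti-Caspr2 captopril mice 1 and 2, and at 7.39%, 8.45% and 4.52% in the other 3. Interferon genes lay below 0 in 28 of 29 cases, median −0.42, with 11 passing when adjusted over the list alone (list adjusted p = 1.20e-09, and adjusted p = 0.310 with an estimated correlation). This came from control mice, where the mean log2 deviation of the list was 0.66 with saline and −0.32 with captopril. Control saline mouse 1 stood at 1.23. In exposed mice the list did not fall, with −0.18 with saline and −0.16 with captopril. Disease-associated genes lay below 0 in 21 of 26 cases, median −0.19, with Axl at −0.85 (SE 0.16, adjusted p = 0.0365) and Cst7 at −0.51 (SE 0.10, adjusted p = 0.0486) as its 2 genes past the threshold in edgeR (list adjusted p = 7.64e-05, and adjusted p = 0.413 with an estimated correlation). Glucocorticoid response genes lay above 0 in 12 of 15 cases, median 0.16, with Nfkbia past the threshold and Ddit4 at 0.87 (SE 0.25; list adjusted p = 0.300 with an estimated correlation). In all 11 of 25 lists passed, 6 higher and 5 lower, and 0 with the estimated correlation or the directional test of fry, while fry called 4 for change in either direction.

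Of 12231 genes 1872 had an unadjusted p under 0.05, and 218 (1.78%) did not overlap between 6 and 6 libraries, where chance gives 0.216%. DESeq2 called 192 genes, including all 56, and limma-voom 71, of which 54 were shared. Leaving out control saline mouse 1, 2 or 3 left 10, 11 and 13 genes, and leaving out anti-Caspr2 saline mouse 1 or 2 left 4 and 7. Leaving out control captopril mouse 1 or 2 left 11 and 14, and leaving out anti-Caspr2 captopril mouse 1 or 2 left 17 and 9. The count was 96 without anti-Caspr2 saline mouse 3 and 293 without anti-Caspr2 captopril mouse 3. The median percentage of mitochondrial UMIs per microglia-like cell was 0.830 to 1.06 in captopril libraries and 1.20 to 1.51 in saline libraries, apart from anti-Caspr2 saline mouse 3 at 0.324. Simulated data of this design recovered 71.6% of genes changed 1.5-fold.

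**Figure D3:**
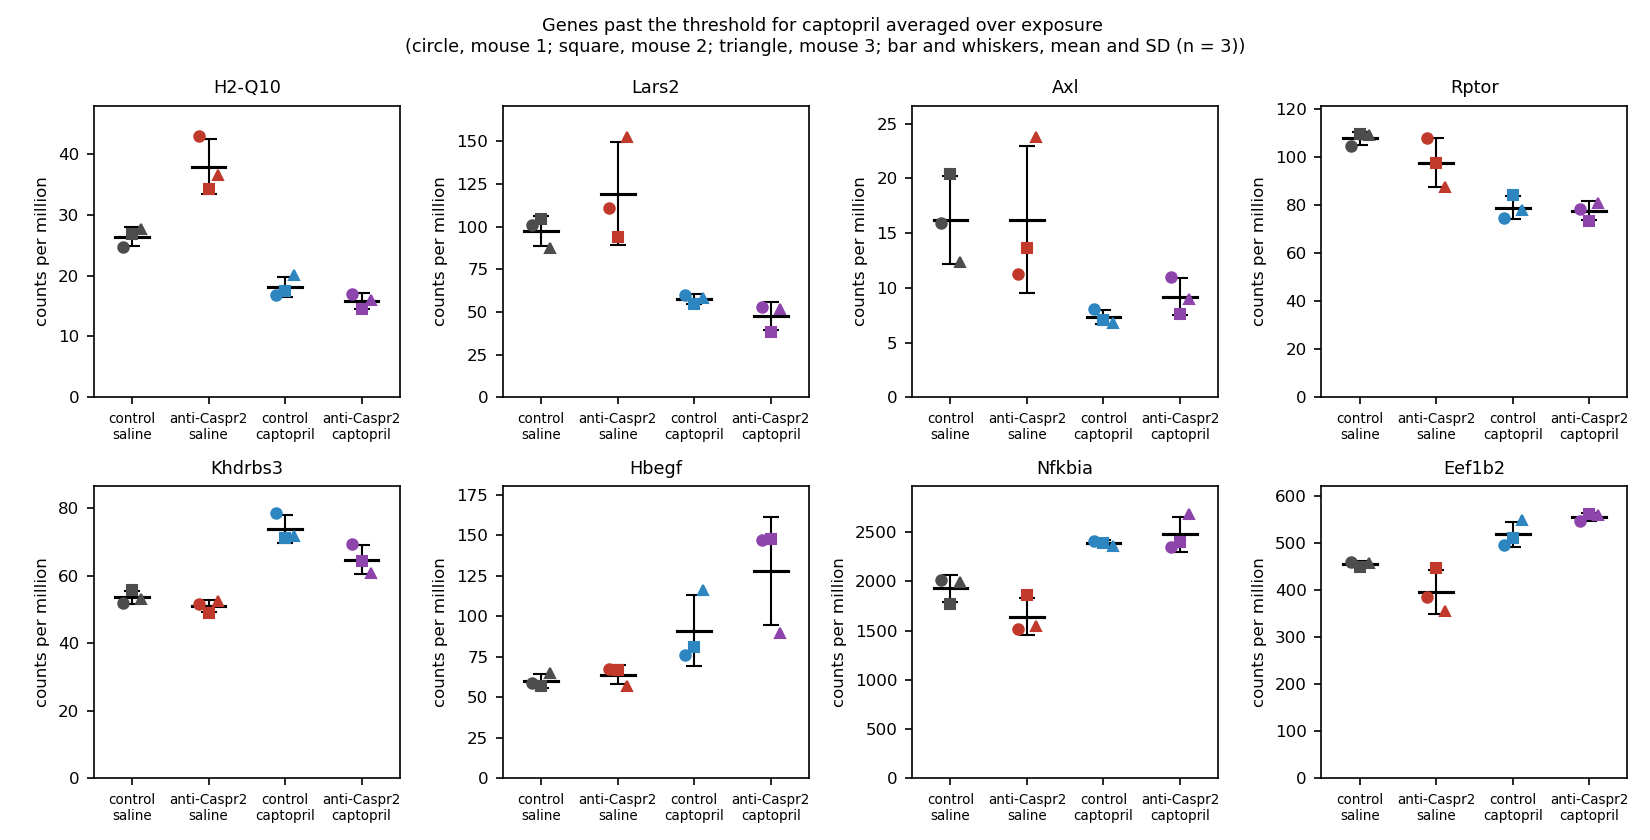
CPM in microglia-like cells of H2-Q10, Lars2, Axl, Rptor, Khdrbs3, Hbegf, Nfkbia and Eef1b2 in the 12 libraries, by group. Points are mice and bars are means with SD (n = 3); H2-Q10 had means of 26.4 and 37.9 CPM in control and exposed saline libraries and of 18.1 and 15.8 CPM with captopril.

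Anti-Caspr2 captopril was also set against control saline, to ask how exposed and treated mice stood against untreated controls. Fam71a, chosen after its values were seen, rose from 3.27 ± 1.47 to 19.2 ± 1.36 CPM (log2 fold change 2.59, SE 0.28, adjusted p = 0.00369 in edgeR, n = 3 each), and Tmem88 rose from 20.5 ± 1.40 to 31.8 ± 1.71 CPM (0.64, SE 0.11, adjusted p = 0.0487). H2-Q10 was lower at −0.75 (SE 0.11, adjusted p = 0.0277), as were Lars2 at −1.03 (SE 0.15) and Gm42418 at −1.35 (SE 0.19), both at an adjusted p of 0.0239, and Cst7 at −0.78 (SE 0.13, adjusted p = 0.0486). Each held in 3 of 3 libraries. Hbegf had 60.1 ± 4.14 and 128 ± 33.4 CPM (1.09, SE 0.19) with an adjusted p of 0.0635. Interferon genes lay below 0 in 28 of 29 cases, median −0.58, with 19 passing when adjusted over the list alone (list adjusted p = 0.370 with an estimated correlation). Among them was the antiviral gene Rsad2 at −2.45 (SE 0.51). Control saline mouse 1 held a list level of 1.23, against 0.41 and 0.33 in control saline mice 2 and 3. The median without that library was not computed for this comparison. Disease-associated genes lay below 0 in 25 of 26 cases, median −0.34, and immediate early genes above 0 in 26 of 28, median 0.36, with Ier5 at 0.52 (both at an adjusted p = 0.370 with an estimated correlation). The immediate early list level was 0.36, 0.23 and −0.12 in anti-Caspr2 captopril mice 1, 2 and 3. In control saline mice it was −0.12, −0.27 and −0.20, so the shift rested mainly on exposed mice 1 and 2. Ribosomal protein genes lay above 0 in 70 of 78 cases, median 0.15, although over all cells they moved the other way (adjusted p = 0.0276), heat shock genes in 19 of 19, median 0.36, and mitochondrially encoded genes below 0 in 13 of 13, median −0.47 (adjusted p = 0.370, 0.371 and 0.379 with an estimated correlation).

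The 11 genes past the threshold were 4 higher and 7 lower of 12231, against 1862 at an unadjusted p under 0.05, 103 with DESeq2 and 15 with limma-voom, and 2746 genes (22.5%) did not overlap, where chance gives 10%. Of 25 lists 13 passed, 4 higher and 9 lower, and 0 with the estimated correlation. The count was 1, 1 and 4 without control saline mouse 1, 2 or 3, and 7, 5 and 21 without anti-Caspr2 saline mouse 1, 2 or 3. It was 4, 3 and 99 without control captopril mouse 1, 2 or 3, and 1, 1 and 545 without anti-Caspr2 captopril mouse 1, 2 or 3.

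Cell shares were compared by exact two-sided permutation tests within strata, with 400 arrangements averaged over the other factor and a smallest p of 0.1 for 3 libraries against 3. Microglia-like cells made up 72.2% ± 19.1 and 72.8% ± 5.70 of cells in control and anti-Caspr2 saline libraries, and 84.8% ± 5.07 and 93.5% ± 1.93 with captopril (SD, n = 3 each). Captopril libraries had 16.6 percentage points more (exact permutation p = 0.025, adjusted p = 0.07, above the threshold), and exposed libraries 4.63 more (exact permutation p = 0.465). Without control saline mouse 2, whose neutrophil-like cells stay in the total, the exposure difference was −0.801 points. Shallow clusters, whose cells had few UMIs and were kept out of the microglia-like class, held 9.87% ± 3.95 and 22.05% ± 6.34 of cells in saline libraries and 12.3% ± 5.11 and 3.98% ± 1.91 with captopril, and can set these shares. Without control saline mouse 1 or 3 or anti-Caspr2 saline mouse 3, the number of class shares past the threshold for captopril was 3, 1 and 1 in place of 0. Border-associated macrophage-like cells made up 5.26% ± 2.75 in control saline and 1.69% ± 2.02 in anti-Caspr2 saline libraries, and 1.61% ± 0.173 and 1.05% ± 0.146 under captopril (exposure difference −2.06 points, exact permutation p = 0.065, adjusted p = 0.26). No captopril test is given for them, since H2-Aa, a leading gene of their cluster, was called for captopril. Neutrophil-like cells made up 22.2% of control saline mouse 2 and at most 0.510% of any other library, and monocyte-like cells 8.36% and at most 1.20%.

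Within microglia-like cells, the cluster led by the immediate early genes Fosb and Egr1 held 9.15% ± 2.77 and 19.1% ± 5.30 in control and anti-Caspr2 saline libraries, and 19.6% ± 20.3 and 33.3% ± 24.9 with captopril (exposure +11.8 points, exact permutation p = 0.135, adjusted p = 0.36; captopril +12.4 points, exact permutation p = 0.19, adjusted p = 0.38). Its share was 7.39%, 8.45% and 43.1% in control captopril mice 1, 2 and 3 and 47.0%, 48.4% and 4.52% in anti-Caspr2 captopril mice 1, 2 and 3. The interferon-led cluster held 2.19% ± 1.36 and 1.31% ± 0.529 with saline and 0.651% ± 0.0641 and 0.835% ± 0.331 with captopril (captopril −1.01 points, exact permutation p = 0.01, adjusted p = 0.06). Of the 3 clusters where the homeostatic list had the most members among the leading genes, the first held 16.7% ± 0.325 and 12.4% ± 6.05 with saline and 22.7% ± 12.2 and 14.2% ± 9.35 with captopril (exposure −6.38 points, exact permutation p = 0.12, adjusted p = 0.36; captopril +3.93 points, exact permutation p = 0.37, adjusted p = 0.493). The second held 11.6% ± 1.77 and 9.19% ± 1.67 with saline and 10.6% ± 2.47 and 9.22% ± 4.64 with captopril (exposure −1.86 points, exact permutation p = 0.255, adjusted p = 0.496; captopril −0.482 points, exact permutation p = 0.775). The third held 26.5% ± 1.80 and 17.1% ± 6.31 with saline and 11.1% ± 3.78 and 11.3% ± 1.67 with captopril (exposure −4.60 points, exact permutation p = 0.125, adjusted p = 0.36). Its captopril values are given without a test, since 1 of its 10 leading genes was called for captopril. Of the clusters compared, 0 passed after adjustment over their family, for exposure or for captopril. In other settings more passed for captopril, 1 without anti-Caspr2 saline mouse 3, 5 with the stricter cell filter, 4 at a clustering resolution of 1.5 and 2 at 0.5.

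**Figure D4:**
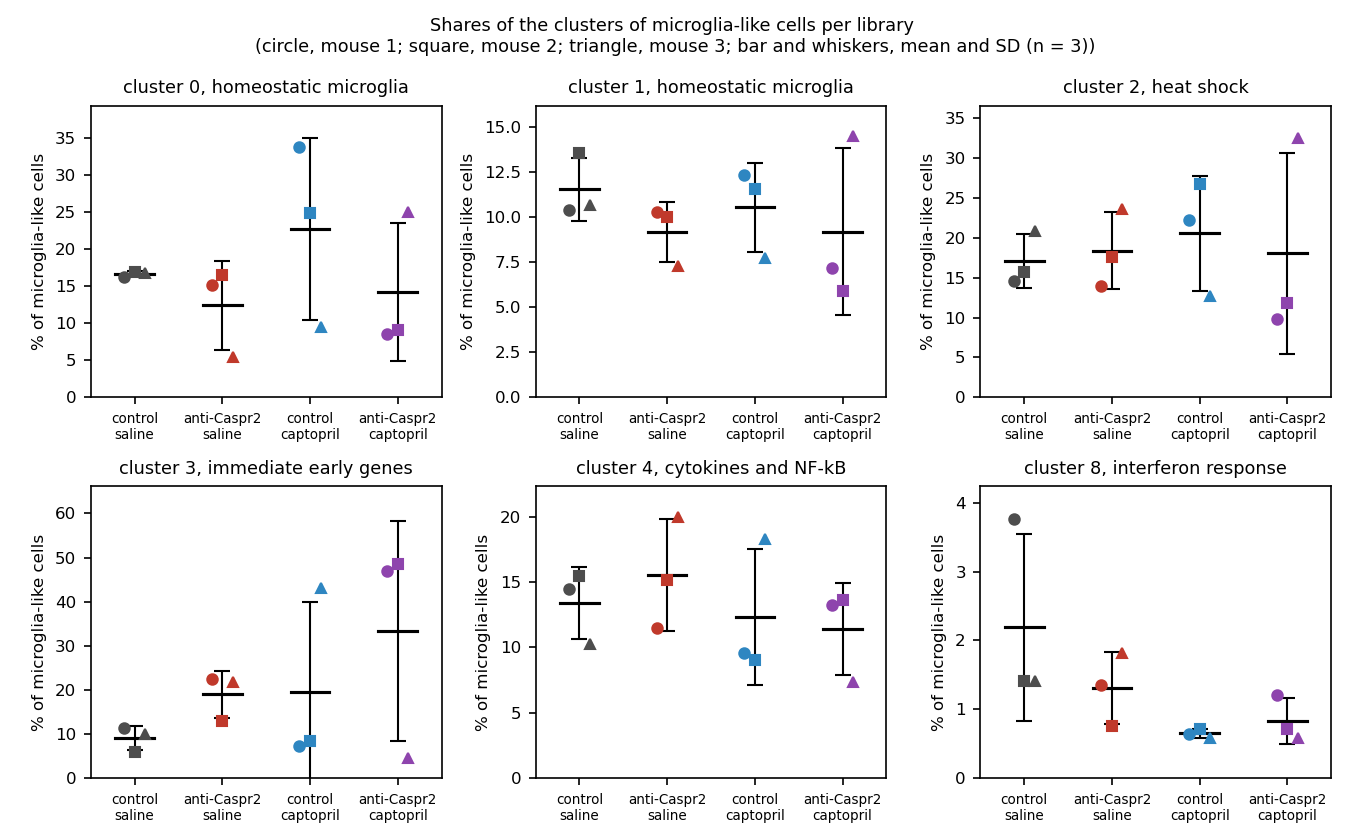
Share of microglia-like cells, in percent, in each of 6 microglia-like clusters, by group, each titled by the fixed list with the most members among its leading genes. Points are mice and bars are means with SD (n = 3); the cluster led by immediate early genes ranged from 4.52% to 48.4% among the captopril libraries.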

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

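The tests of explanations and of other groupings of the libraries in this part were chosen only after the results were seen. The interaction test itself was chosen before.

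Interferon response genes had a median interaction of 0.75 on the log2 scale, which passed by camera with its preset correlation but not with an estimated one (adjusted p = 0.731). Usp18, Rtp4 and Bst2 had 9.05, 14.9 and 118 CPM in control saline and 4.75, 6.18 and 78.3 CPM in anti-Caspr2 saline libraries. Disease-associated genes such as Cd63 had a median interaction of 0.16, and ribosomal protein genes one of 0.17, although Rps29 went the other way at −0.94. None of the 3 lists passed with an estimated correlation (adjusted p = 0.731 for each), and all of 100 random splits of the libraries gave as many lists as the real split, with up to 16, so chance cannot be excluded. For single genes the interaction gave 0 with edgeR, 565 at an unadjusted p under 0.05 and 1 with DESeq2, while another split gave 2884. A count of 0 is reached by every split, so this says nothing about chance.

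The lower interferon genes in anti-Caspr2 saline libraries were weighed against control saline mouse 1, whose list level was 1.23 against 0.41 and 0.33 in control saline mice 2 and 3. Leukocytes of control saline mouse 2 are argued against, since without that library the median was −0.64 in place of −0.59. Without mouse 1 the median was −0.27 and without the interferon-led cluster −0.24, so either may account for part of the difference. Whether the rest differs from 0 was not tested. The genes of the list differed widely, with a median absolute deviation of 0.59. This is a spread between genes and not between mice, so it cannot decide, and both stay open. In utero exposure may also contribute, and stays untested beyond the comparison itself.

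Captopril averaged over exposure changed 56 genes, including lower H2-Q10, Lars2 and Rptor and higher Hbegf and Nfkbia. Of 100 splits of the libraries, the others drawn at random, only 1, the real one, reached a count this large. The highest other drawn was 8, so a chance result is unlikely for the count of genes, though not excluded. Cells of the immediate early cluster are argued against, since 50 of the 56 genes stayed past the threshold without them. Shallow clusters were left out of the tested sums, so their number of cells cannot move these values directly. RNA like theirs within microglia-like cells could contribute, since 89.3% of the called genes moved as fewer shallow cells would move them, against 62.9% of all genes. Shallow cluster 10 held 7.56% and 17.1% of cells in control and anti-Caspr2 saline libraries against 3.18% and 1.61% with captopril. All shallow clusters together, however, held 12.3% in control captopril against 9.87% in control saline libraries. That mean was raised by cluster 7 with 14.0% in control captopril mouse 3. Whether such RNA contributed stays open. A library batch cannot be told apart from captopril, since 0 libraries have drug and first number apart.

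Immediate early genes such as Fosb and Egr1 led a cluster that held 43.1% of microglia-like cells in control captopril mouse 3 and 47.0% and 48.4% in anti-Caspr2 captopril mice 1 and 2, but 4.52% in anti-Caspr2 captopril mouse 3. Exposure called 0 genes in captopril with edgeR, with 327 at an unadjusted p under 0.05 and 1 with DESeq2. The split that exchanges the 2 captopril libraries of mouse 3 called 3036, which points to a structure of the samples other than their labels. With that exchange the correlation with exposure in saline was 0.313 in place of 0.129, which is consistent with exchanged labels but also with a dissociation response that differed between libraries, and cannot be told apart from either. The 3 libraries have adjacent library numbers, but so have 0.2 of all triplets of the 6 captopril libraries.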

How the results depend on the processing

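The single-cluster fit, the shallow-cluster fit, the fits with surrogate variables, the coarser and finer clustering for gene tests, the fit without the interferon-led cluster and the fit without 2 libraries were chosen only after the results were seen. The rest of the 37 alternatives were chosen before the data were examined. Where a value below moved, the cause was not tested, except that leaving out libraries, thinning and equal cell numbers leave fewer data.

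H2-Q10 and Lars2 kept their direction for captopril averaged over exposure in each alternative run, and each stayed past the threshold in 30 of 31 alternatives, the exception being an equal number of cells. Fam71a stayed past the threshold in 29 of the 29 settings that tested it, fewer than the 31 of H2-Q10 and Lars2. For captopril in exposed mice Fam71a stayed in 21 of 30. The following were lost more often for captopril averaged over exposure. Of 31 settings, Khdrbs3 stayed past the threshold in 25, Gm42418 in 24, Rptor in 20, Nfkbia in 19, Rbm4 and Klf10 in 17, Hbegf, Adcy7, Lncpint, Rpl31, Trappc6b and Utp3 in 16, Madd in 15, Eef1b2 in 14, Kdm3b in 13 and Dnmt3a in 12, and of 29 settings Axl in 17 and Cst7 in 11. Of 28 settings, Adm stayed in 17 and H2-Aa in 14. The change of Kdm3b was as small as −0.02. The count for captopril averaged over exposure was 56 genes. It was 192 with DESeq2, 106 with no filter beyond a total above 0, 158 with the stricter cell filter, 9 after thinning to the smallest library and 2 with an equal number of cells. It was 189 without the immediate early cluster, of which 50 were shared, 434 with the shallow clusters, of which 55 were shared, and 164 in cluster 9 alone, of which 13 were shared. It was 37 and 539 with 1 and 2 surrogate variables, and 10 without control saline mouse 2 and anti-Caspr2 saline mouse 3. Leaving out 1 library gave 4 to 293.

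For captopril in exposed mice, where 4 genes passed, the counts were 63 with DESeq2, 8 with no filter, 10 with the stricter cell filter, 0 over all cells, 2 with equal cells, 12 without the immediate early cluster, 57 with the shallow clusters, 101 in cluster 9 and 53 with 2 surrogate variables, and 1 to 6 when 1 library was left out. For captopril in control mice, where 0 passed with edgeR and 1157 had an unadjusted p under 0.05, they were 64 with DESeq2, 32 with no filter, 1 with only the groups compared, 46 without the immediate early cluster, 32 with the shallow clusters, 66 in cluster 9 and 319 with 2 surrogate variables, and 0 to 36 when 1 library was left out. For anti-Caspr2 captopril against control saline, where 11 passed, they were 103 with DESeq2, 54 with no filter, 4 at a mean of at least 20 CPM, 1 over all cells, 4 after thinning, 2 with equal cells, 42 without the immediate early cluster, 4 without the interferon-led cluster, 57 with the shallow clusters, 52 in cluster 9, 21 and 324 with 1 and 2 surrogate variables and 2 without the 2 libraries, and 1 to 545 when 1 library was left out.

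For exposure, edgeR called 0 genes in each comparison as designed, with 1172, 327, 927 and 565 at an unadjusted p under 0.05 in saline, in captopril, averaged and for the interaction, and 0 when any 1 library was left out. In saline the count was 13 with DESeq2, 1 with no filter, 8 with only the groups compared and 12 in cluster 9. In captopril it was 1 with DESeq2, after thinning, with equal cells and in cluster 9. For the interaction it was 1 with DESeq2, 1 after thinning and 12 in cluster 9, and averaged over drug it was 1 with DESeq2, 5 in cluster 9 and 1 with 2 surrogate variables. Elavl4 passed with DESeq2 (adjusted p = 0.00615) and with 2 surrogate variables (adjusted p = 0.0121), and over all alternatives its adjusted p was 0.00615 to 0.824.

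With an estimated correlation, and with the directional test of fry, 0 lists passed in each of the 8 comparisons, against 9 and 1 for exposure in saline and in captopril, 4 and 15 for captopril in exposed and control mice, 13 for anti-Caspr2 captopril against control saline, 3 for the interaction, and 10 and 11 for exposure and captopril averaged. For change in either direction, fry called 1, 4, 5 and 4 lists for captopril in exposed mice, in control mice, for anti-Caspr2 captopril against control saline and for captopril averaged, and 0 in the others. Over all cells the counts were 2 for exposure in captopril and 10 for the interaction, and after thinning they were 3 for exposure in captopril, 8 for captopril in control mice and 7 for captopril averaged. Leaving out 1 library gave 6 to 12 and 1 to 7 lists for exposure in saline and in captopril, 3 to 6 and 10 to 16 for captopril in exposed and control mice, 10 to 15 for anti-Caspr2 captopril against control saline, 2 to 9 for the interaction, and 7 to 11 and 8 to 14 for exposure and captopril averaged.

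Some lists changed direction over all cells, where other cell types add their RNA. The homeostatic list had an adjusted p = 0.128 for exposure in saline and 0.470 for exposure averaged (with 1 library left out, 0.000100 to 0.0260 and 9.01e-06 to 0.0293). The nuclear-encoded oxidative phosphorylation list had 5.81e-06 for captopril in control mice and 0.0950 for captopril averaged (4.86e-08 to 0.176 and 2.44e-06 to 0.0950). The ribosomal list had 0.0181 for captopril in control mice and 0.0276 for anti-Caspr2 captopril against control saline (3.36e-19 to 3.04e-07 and 1.58e-17 to 0.000120). The oxidative stress list had 0.251 and 0.508 in these comparisons (0.00216 to 0.189 and 0.00337 to 0.171), and the lysosome list had 0.970 for captopril averaged (0.000950 to 0.139). The mitochondrially encoded list reversed for exposure in saline without control saline mouse 2 and anti-Caspr2 saline mouse 3, with an adjusted p = 0.589, and gave 9.97e-07 to 0.829 when 1 library was left out.

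The correlation of exposure effects between drugs was 0.329 at a mean of at least 20 CPM, −0.0325 over all cells and 0.0225 to 0.186 when 1 library was left out. The correlation of exposure in saline with captopril in exposed mice was −0.338, −0.248 and −0.748 to −0.411 in the same settings.

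The identity genes lay near 0 and changed sign in several settings (log2 fold changes). P2ry12 for exposure in saline gave 0.00226 and 0.0667 with 1 and 2 surrogate variables, 0.0968 over all cells and 0.00422 with equal cells, and −0.147 to −0.0504 when 1 library was left out. P2ry12 for captopril in exposed mice gave −0.0997 and −0.0436 with 1 and 2 surrogate variables, −0.000321 with DESeq2, −0.000160 with the stricter cell filter, −0.195 with equal cells, −0.0452 at 20 CPM, −0.0165 with only the groups compared, −0.0380 after thinning, −0.0419 without the 2 libraries, and −0.0991 to 0.0778 when 1 library was left out. Tmem119 for exposure in saline gave 0.0931 over all cells, 0.00692 with equal cells and −0.105 to −0.0816 when 1 library was left out. Tmem119 for captopril in exposed mice gave −0.129 with equal cells, −0.0155 at 20 CPM, −0.0459 after thinning and −0.0433 to 0.107 when 1 library was left out. Cx3cr1 for exposure in saline gave −0.00831 with no filter, −0.0145 with the shallow clusters, −0.0256 without the 2 libraries and −0.0585 to 0.0636 when 1 library was left out. Cx3cr1 for captopril in exposed mice gave 0.0553 over all cells, 0.0158 with no filter, 0.00159 with finer clustering, 0.00751 with the stricter cell filter, 0.0291 with the shallow clusters, 0.0503 without the immediate early cluster and −0.106 to 0.0594 when 1 library was left out. Apoe for exposure in saline gave 0.0129 with finer clustering, 0.0838 with the stricter cell filter, 0.0446 without the immediate early cluster and −0.522 to 0.241 when 1 library was left out. Hlf for exposure in captopril gave 0.136 with equal cells and −0.561 to −0.369 when 1 library was left out.

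The mouse number was fitted as a replicate block, although each mouse came from its own litter. The 18 pairs of libraries with the same number correlated at −0.545 to 0.161, median −0.0234, against 0.00512 for other numbers, 2 pairs lay above 0.1, and 1 of 12 libraries correlated best with its own number, so the numbers do not pair the samples. With the block 8 genes passed for captopril averaged and 3 for anti-Caspr2 captopril against control saline, and 2 lists for exposure in captopril.

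No share passed for captopril after adjustment as designed. With 1 library left out 0 to 3 class shares and 0 to 1 cluster shares passed for captopril, and 0 of either for exposure. Cluster shares past the threshold for captopril numbered 2 at a resolution of 0.5, 4 at 1.5 and 5 with the stricter cell filter. When 1 library was left out, the exposure difference of microglia-like cells was −0.801 to 8.21 points, of monocyte-like cells −1.96 to 0.133, of neutrophil-like cells −5.41 to 0.115, of cluster 2 −4.22 to 1.45, of cluster 4 −0.494 to 2.12 and of cluster 8 −0.545 to 0.0432. The captopril difference was −5.52 to 0.00494 for neutrophil-like cells, −1.81 to 0.339 for cluster 1 and −2.06 to 3.61 for cluster 2. Depth limits anti-Caspr2 saline mouse 3, whose 618688 UMIs set the thinned level.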

Other observations

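The counts of other splits in this part were chosen only after the results were seen.

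Basophil genes Mcpt8 and Prss34 led a cluster of 26 cells, 88.5% of them from control saline mouse 2, the library that also held most neutrophil-like cells. A cluster of 347 cells carried the cell cycle genes Top2a and Mki67 beside Pf4 and Ms4a7, and stayed unnamed. It made up 1.92% ± 0.837 and 2.69% ± 0.915 of cells in control and anti-Caspr2 saline libraries and 0.992% ± 0.522 and 1.01% ± 0.388 with captopril (SD, n = 3 each). Neutrophil precursor genes Elane, Prtn3 and Mpo led 25 cells, all from 1 library.

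H2-Q10, Lars2 and Fam71a were called for captopril in exposed mice, where 1 of 10 splits, the real one, gave as many genes as the 4 seen and the highest other gave 0. For anti-Caspr2 captopril against control saline, 1 of 10 splits gave 11 genes and the highest other 0. Exposure in saline and captopril in control mice gave 0 genes with edgeR (1172 and 1157 at an unadjusted p under 0.05, 13 and 64 with DESeq2) and 0 in the highest other of 10 splits. A real count of 0, as for exposure in captopril too, is reached by 10 of 10 splits whatever the data, so it says nothing about chance. Splits of 3 libraries against 3 number 10, too few for a share under 0.05.

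Interferon and disease-associated genes were among the 9 lists of exposure in saline, where 5 of 10 splits gave as many and the highest other 11. Oxidative phosphorylation was the 1 list of exposure in captopril, where 10 of 10 splits gave as many and the highest other 8. Ribosomal and immediate early genes were among the 4 lists of captopril in exposed mice, where 9 of 10 splits gave as many and the highest other 9. For captopril in control mice 15 lists passed, reached by 1 of 10 splits, with 11 in the highest other, and for anti-Caspr2 captopril against control saline 13 passed, reached by 2 of 10, with 13 in the highest other.

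Elavl4 led exposure averaged over drug, where edgeR called 0 genes (927 at an unadjusted p under 0.05, 1 with DESeq2). A count of 0 is reached by all of 100 splits drawn at random whatever the data, so this says nothing about chance for Elavl4 or for exposure. The highest other split drawn gave 1590 genes. For its 10 lists 21 of 100 splits gave as many, with 16 in the highest other. The correlation of exposure effects between saline and captopril, 0.129, was reached by 16 of 100 splits drawn at random, with 0.233 in the highest other of those drawn. The exchange of the 2 captopril libraries of mouse 3 was not among them and gave 0.313. For the 11 lists of captopril averaged over exposure, ribosomal proteins first by p, 13 of 100 splits gave as many, with 15 in the highest other. Chance cannot be excluded for these.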
